A study of Homo sapiens with 6 samples.

How the data were processed

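RNA sequencing counts of the human small cell lung cancer line NCI-H69 were analysed for 3 libraries of cells given the vehicle DMSO and 3 of cells given the ABL kinase inhibitor GNF5 for 48 h. Groups and replicate numbers came from the treatment labels and titles. The labels give the GNF5 dose once in micromolar and once in millimolar. The value per sample, 20 µM, was used here, and the conflict is unresolved. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Whether libraries were made by poly(A) selection or ribosomal RNA depletion is not given in the sources used here.

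The deposited values are raw counts per gene, not normalised. Per the file headers, the authors counted read pairs as fragments with featureCounts 1.6.1, in reverse-stranded mode, over exons summed by gene, with the Ensembl release 101 annotation of GRCh38 and default handling of multi-mapped reads and of reads that overlap several genes. In that default such reads are left out, so genes with near-identical copies or shared exons are undercounted. The submitters' processing notes name Trim Galore, STAR, HTSeq, DESeq2 and GRCh37 without versions or roles. HTSeq and GRCh37 differ from the file headers, and the headers were followed for the counter, the annotation and all coordinates. The genome build of the alignment itself was not settled by these sources.

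Each file held 60671 gene rows and no summary rows. Symbols came from a gene name table, which had an entry for 60401 of these IDs. Symbols were looked up by ID, and the remaining 270 IDs kept their ID as a name. GC content was taken from GENCODE 29 transcripts, which covered 98.3% of the tested genes. Total counts ran from 46148701 to 60697602 per library. A gene with 3 counts lay between 0.0494 and 0.065 counts per 1000000 counts (CPM) in these libraries. Intervals and limits of this kind cover counting error only, since the reads carry no stated molecular identifiers. The counts of every pair of libraries in a group differed by more than sampling noise (chi-square over degrees of freedom 3.13 to 8.79), and all 6 libraries were kept.

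The comparison of GNF5 with DMSO used edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test (robust fit), TMM normalisation, no covariate and Benjamini-Hochberg adjustment. Genes were called at an adjusted p under 0.05. The default expression filter kept 20734 genes and removed 39937, which held 0.063% of all counts. CPM values are TMM-normalised, and "mean log2 CPM" is edgeR's average over the 6 libraries. The standard error (SE) of a log2 fold change was back-calculated as its size divided by the square root of the F statistic. Gene lists were tested with camera (limma 3.58.1, voom weights, two-sided), with a preset inter-gene correlation of 0.01 and adjustment over the 32 lists with at least 5 tested genes. Camera compares a list with all other genes. Camera with an estimated correlation was run beside it, as was fry, whose directional test asks whether a list's genes move, on balance, one way without comparing them with other genes.

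The choices in this paragraph, apart from the names in its closing sentences, were made before the data were examined. The 34 gene lists covered ABL kinases and adaptors; origin licensing and the replicative helicase; replication fork polymerases and clamp; the ATR checkpoint and fork protection; the Fanconi anemia pathway; homologous recombination; R-loop resolution and transcription-replication conflict factors; RNA polymerase II subunits and elongation factors; p53 targets; G1/S and E2F targets; G2/M and mitosis; replication-dependent histones; targets of ATF4 in the integrated stress response; the unfolded protein response; cholesterol synthesis and SREBP2 targets; fatty acid synthesis and SREBP1 targets; the interferon response; neuroendocrine markers; non-neuroendocrine and mesenchymal markers; NOTCH signalling; the MYC family and targets; cytosolic ribosomal proteins; mitochondrially encoded genes; nuclear-encoded oxidative phosphorylation genes; glycolysis and hypoxia; NRF2 and oxidative stress; lysosome and autophagy; apoptosis; immediate early and AP-1 genes; heat shock; and markers of fibroblasts, leukocytes, lung epithelium and erythroid cells. The genes named are ABL1, ABL2, MYCN, NEUROD1, POU2F3 and YAP1, then the 10 called genes with the largest change in each direction, and up to 4 called members of each list with the lowest p-values. The genes of largest change needed a mean log2 CPM of at least 1, no overlap between the groups and a symbol that is not a clone or pseudogene name, and list members needed the same mean level. Members that moved against their list or were not called, and markers of other cells below that level, were named after their values were seen. Some genes that the rule takes are not reported here, and no others took their place.

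Alternatives were DESeq2 size factors, upper-quartile factors, no filter, a filter of at least 10 counts in each of 3 libraries with a mean log2 CPM of at least 1, the DESeq2 1.42.0 test, limma voom, the replicate number as a block, each library left out in turn, removal of mitochondrial genes and the 20 most abundant genes, an adjusted p under 0.01, and the other list tests. Added after seeing the data were thinning of every library to the smallest total, removal of GC and length trends (mgcv 1.9.3), and a test against a 1.5-fold change. The share of each named gene's exon bases that lies in an exon of another gene on the same strand was computed from the annotation in the files.

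The procedure was tested on counts simulated from the means and library sizes of these samples, over 20361 genes with 200 changed. EdgeR recovered 54% of the genes changed 1.25-fold, 70% at 1.5-fold, 84% at 2-fold and 96% at 4-fold, and 6.7% of its calls fell on unchanged genes. In the same simulation camera called both changed lists and 0 of 30 unchanged ones, and fry and camera with an estimated correlation did likewise. The simulated genes varied independently, whereas the estimated correlation in the data reached 0.697, for cytosolic ribosomal proteins. The simulation therefore cannot show how the list tests behave with correlated genes. In the data 61.6% of tested genes were called, so the simulated rates of recovery and false calls may not carry over. Figures were drawn with matplotlib 3.10.9.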

Results

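The transcriptome of NCI-H69 cells was measured by RNA sequencing after 48 h with GNF5 or with its vehicle DMSO, with 3 libraries in each group. NCI-H69 is an established small cell lung cancer line of the neuroendocrine type that carries amplified MYCN. GNF5 is an allosteric inhibitor that binds the myristoyl pocket of the ABL kinases, used here at 20 µM. The title of the series asks whether loss of ABL kinase activity raises conflicts between transcription and replication and weakens replication forks. The DMSO libraries held 56467189, 60697602 and 57885182 counts and the GNF5 libraries 58771023, 46148701 and 52414089. Below, log2 fold changes are GNF5 against DMSO with their SE, levels are counts per 1000000 counts (CPM) with the SD over 3 libraries, and every gene said to have risen or fallen passed edgeR's quasi-likelihood test.

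With GNF5, genes of cell division, glycolysis and hypoxia, and sterol and fatty acid synthesis were lower, and targets of the stress factor ATF4 and genes of the unfolded protein response were higher. With an estimated correlation between genes, the cell division lists of G2/M and of G1/S genes passed (adjusted p = 0.0198 and 0.0359), while glycolysis and hypoxia (adjusted p = 0.135), sterol synthesis (0.0552), fatty acid synthesis (0.131), ATF4 targets (0.105) and the unfolded protein response (0.0782) did not. LDHA, the enzyme that makes lactate, fell from 2078 ± 97.7 to 358.5 ± 10.1 CPM. It had the lowest p-value of the genes named by the rule set beforehand and reported here. GDF15, a secreted stress cytokine, rose from 96.6 ± 5.65 to 538.3 ± 16.1 CPM. Of 20734 genes tested, 6426 were higher and 6356 lower with GNF5. At least 2-fold changes were seen for 1026 higher and 1388 lower genes, or 413 and 494 with the stricter filter, which left 13953 genes to test. The median absolute log2 fold change of the called genes was 0.46. The 3 values of a gene in one group all lay on one side of those in the other for 65.9% of tested genes, where chance gives 10%. Against a 1.5-fold change, a test added after seeing the data, 1240 genes were higher and 1560 lower.

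**Figure D1:**
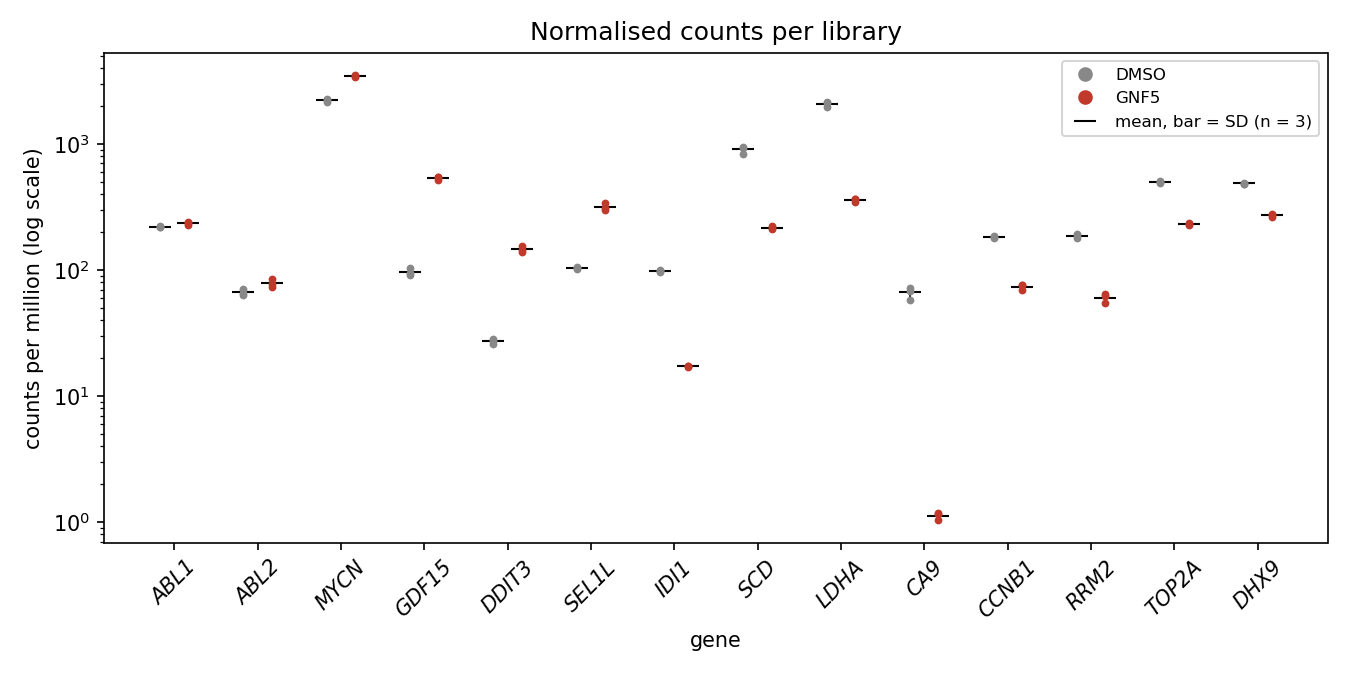
Normalised CPM (log axis) in each library for 14 genes, with grey points for DMSO, red points for GNF5 and black marks for the mean with its SD (n = 3 each). The GNF5 points lie above those of DMSO for GDF15, DDIT3 and SEL1L and below them for CA9, LDHA, IDI1 and SCD.

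The kinases that GNF5 targets changed little at the RNA level, while MYCN rose and NEUROD1, low in both groups, fell. ABL1 (ENSG00000097007, chromosome 9, 130713016 to 130887675, GRCh38) had 220.5 ± 2.42 CPM with DMSO and 234.6 ± 5.68 with GNF5, a log2 fold change of 0.09 ± 0.032 (edgeR adjusted p = 0.0173). That call was lost with upper-quartile factors (log2 fold change 0.064, adjusted p = 0.0858) and without DMSO replicate 1 (0.079), DMSO replicate 3 (0.082) or GNF5 replicate 3 (0.076). Its adjusted p over all alternatives ran from 0.00209 to 0.0951. ABL2 (ENSG00000143322, chromosome 1, 179099330 to 179229684) rose by 0.24 ± 0.047. MYCN (ENSG00000134323, chromosome 2, 15940550 to 15947007) rose from 2213 ± 62.1 to 3448 ± 51.6 CPM, which is 1.56-fold. NEUROD1 (ENSG00000162992, chromosome 2, 181673088 to 181680547) was low and fell from 1.63 ± 0.342 to 0.755 ± 0.119 CPM. POU2F3, the factor of the tuft-like subtype, had 5 counts in all 6 libraries together. YAP1 had 0 counts in them, which allows a level of up to 0.00903 CPM. Among the 14 genes of the ABL kinases and adaptors list, 6 rose and 3 fell, led by NCK2 (0.84 ± 0.078), with ABI2 higher (0.17 ± 0.045) and BCAR1 lower (-0.18 ± 0.055). That list did not pass (camera adjusted p = 0.526).

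The largest rises were in genes that were almost silent with DMSO. OSCAR (ENSG00000170909, chromosome 19, 54094668 to 54102692), an osteoclast-associated receptor, rose from 0.776 ± 0.133 to 20.7 ± 1.41 CPM, which is 26.6-fold. F7 (ENSG00000057593, chromosome 13, 113105788 to 113120685), coagulation factor VII, rose 24.8-fold, and LMX1A (ENSG00000162761, chromosome 1, 165201867 to 165356715), a LIM homeobox factor, rose 23.3-fold to 57.3 ± 2.53 CPM. KLHDC7B, NIBAN1, CDC42EP1, LAMP3, CCND2, PRSS1 and KCNA5 followed, with log2 fold changes from 4.39 to 3.46. PRSS1 has near-identical trypsinogen copies, so its value is uncertain.

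The largest falls included several genes that hypoxia is known to induce. CA9 (ENSG00000107159, chromosome 9, 35673918 to 35681159), a carbonic anhydrase, fell from 66.4 ± 7.47 to 1.13 ± 0.078 CPM. SLC16A3 (ENSG00000141526, chromosome 17, 82228397 to 82261129), which exports lactate, fell from 105.9 ± 9.01 to 3.59 ± 0.475 CPM. ALDOC, LOXL2 and NDRG1 fell (log2 fold changes -4.65, -3.43 and -3.42). The antisense RNA HIF1A-AS3 (ENSG00000258667, chromosome 14, 61707564 to 61751099, counted by strand) had 1510 counts over the DMSO libraries and 3 over the GNF5 libraries, a ratio of 452 after scaling (95% exact interval 155 to 2200, counting error only). The imprinted RNA H19 (ENSG00000130600, chromosome 11, 1995176 to 2001470) fell by 5.40 on the log2 scale. It had 212, 244 and 260 counts in the DMSO libraries but only 12, 0 and 3 in the GNF5 libraries, so the size of its fall is uncertain. PLA2G3, DNAH11 and PDE4C complete the 10, although 70.7% of the exon bases of PDE4C lie in another gene model on the same strand and its value is uncertain.

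Across the gene lists fixed beforehand, camera called 3 higher, led by the targets of ATF4, and 12 lower of 32 tested. With an estimated correlation 4 of these calls held, all lower with GNF5, namely G2/M and mitosis, G1/S and E2F targets, origin licensing, and fork polymerases. The estimates rest on 6 libraries and differed between lists. They were -0.009 for origin licensing and -0.037 for fork polymerases, against 0.511 for glycolysis and hypoxia and 0.3 for ATF4 targets. Which calls held therefore depends on these estimates as well as on the size of the changes. Of the 10 ways of splitting the 6 libraries, each other than the real one also gave 10 to 15 lists by camera. EdgeR called 0 genes in each of them, and camera with an estimated correlation called 0 lists. Camera with the preset correlation can thus call lists where no gene passes. Such a split mixes the treatments and keeps part of their difference between its groups, so it does not show what chance would give. Adjusted over the list alone, the counts of higher and lower genes were identical for 28 of the 34 lists, and in the other 6 a count moved by 1.

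**Figure D2:**
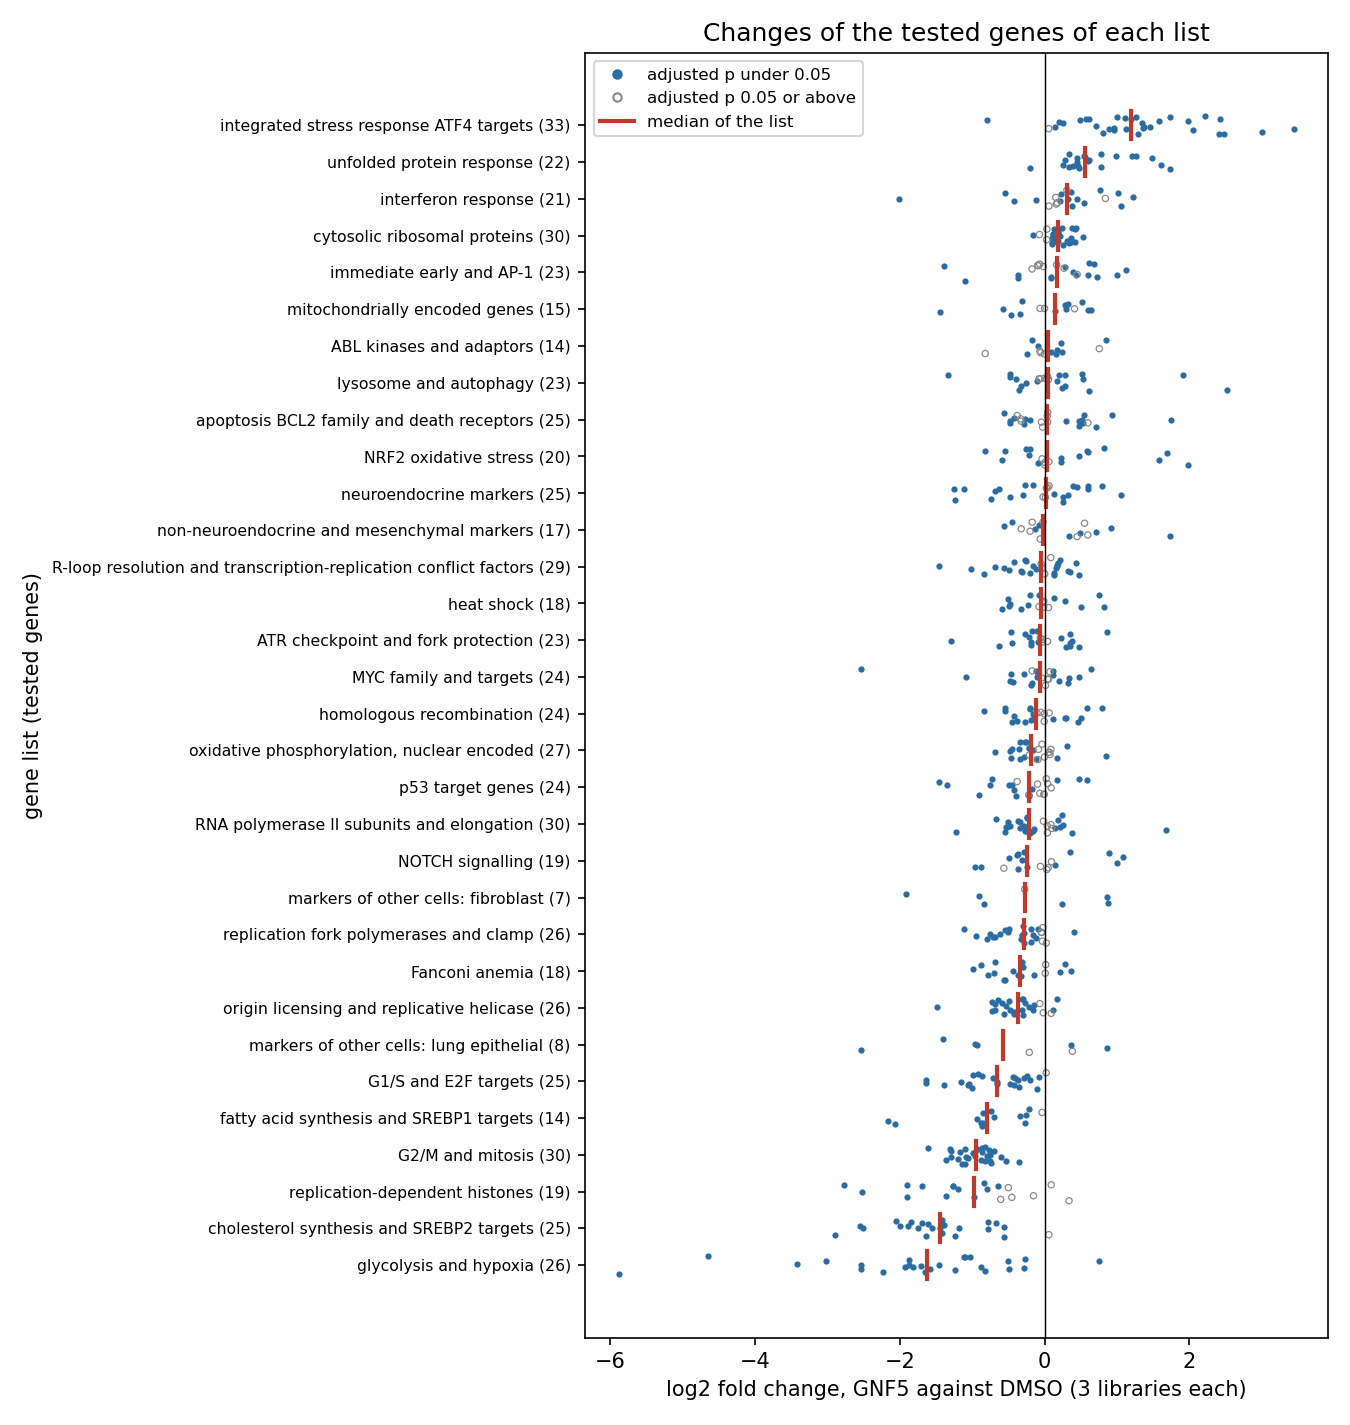
Log2 fold changes (x axis, GNF5 against DMSO, 3 libraries each) of the tested genes of 32 gene lists (y axis, with the number tested), sorted by median. Filled points passed edgeR's test, open points did not, and red bars mark the list medians, which run from -1.62 for glycolysis and hypoxia to 1.19 for the targets of ATF4.

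Genes of cell division fell together. All 30 genes of the G2/M and mitosis list were lower, with a median log2 fold change of -0.95 (camera adjusted p = 4.27e-22, and adjusted p = 0.0198 with an estimated correlation). CCNB1, the mitotic cyclin, fell from 183 ± 2.81 to 74.0 ± 3.6 CPM, and KIF20A, PLK1 and HMMR fell (log2 fold changes -1.61, -1.29 and -1.36). Of 25 G1/S and E2F targets, 24 fell (median -0.65, camera adjusted p = 4.61e-13, and adjusted p = 0.0359 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell from 187 ± 5.82 to 60.5 ± 4.97 CPM, and CCNE2 and CCNA2 fell (log2 fold changes -1.04 and -1.15). E2F1 was the remaining gene, at a log2 fold change of 0.02 ± 0.034. Of 19 replication-dependent histone genes, 13 fell and 0 rose (median -0.98, camera adjusted p = 4.79e-06, but adjusted p = 0.135 with an estimated correlation). H1-2, H2BC11, H2AC6 and H2BC12 fell (log2 fold changes -1.91, -1.90, -1.36 and -1.27). Histone genes resemble each other in sequence and most of their RNAs lack a poly(A) tail, so their levels are uncertain.

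Genes of the replication machinery also fell, by less. Of 26 genes of origin licensing and the replicative helicase, 21 fell and 2 rose, or 3 rose adjusted over the list alone (median -0.37, camera adjusted p = 2.98e-07, and adjusted p = 0.0359 with an estimated correlation). TICRR, an origin firing factor, fell from 29.7 ± 1.06 to 10.6 ± 0.393 CPM, and CDC45, ORC6 and GINS1 fell (log2 fold changes -0.68, -0.72 and -0.59). The origin recognition genes ORC4 (0.18 ± 0.053) and ORC2 (0.12 ± 0.045) were those that rose. Of 26 fork polymerase and clamp genes, 20 fell and 1, POLD4, rose (median -0.29, camera adjusted p = 7.95e-07, and adjusted p = 0.0359 with an estimated correlation). TOP2A, which untangles DNA, fell from 498.7 ± 11.4 to 231 ± 4.14 CPM, PCNA, the sliding clamp, from 419.5 ± 10.2 to 249.4 ± 12.4, and POLA1 and FEN1 fell (log2 fold changes -0.80 and -0.95). Of 18 Fanconi anemia genes, 13 fell and 3 rose (median -0.34, camera adjusted p = 0.00188, but adjusted p = 0.0983 with an estimated correlation), led by UBE2T, BRIP1, FANCI and UHRF1 at -0.70, -0.78, -0.55 and -0.98.

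The checkpoint and repair lists were mixed. In the ATR checkpoint and fork protection list, 8 of 23 genes rose and 11 fell (camera adjusted p = 0.526). CDC25C, CLSPN and CDC25A fell (log2 fold changes -1.30, -0.63 and -0.46), whereas WEE1, the kinase that holds CDK1 inactive, rose by 0.29 ± 0.034. In homologous recombination 7 of 24 genes rose and 12 fell (camera adjusted p = 0.497), with RAD52 higher (0.79 ± 0.057) and GEN1, XRCC3 and BLM lower (-0.83, -0.54 and -0.54). Of 24 p53 targets, 12 fell and 3 rose (median -0.22, camera adjusted p = 0.00723, but adjusted p = 0.135 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, fell from 615.3 ± 12.3 to 365.1 ± 15.1 CPM, and TP53INP1, PLK2 and BTG2 fell (log2 fold changes -1.46, -0.91 and -0.73).

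Genes that act on R-loops and at conflicts of transcription with replication went both ways. Of 29 tested, 11 rose (12 adjusted over the list alone) and 14 fell, with a median of -0.05 (camera adjusted p = 0.33). The helicase DHX9, which unwinds RNA-DNA hybrids, fell from 486.9 ± 5.66 to 271.6 ± 7.39 CPM. PIF1, SRSF1 and DDX23 fell (log2 fold changes -1.46, -0.69 and -0.50), and 32.7% of the exon bases of SRSF1 are shared with another gene model that was too low to test. Of 30 genes of RNA polymerase II and elongation, 18 fell and 7 rose (median -0.22, camera adjusted p = 0.0303, but adjusted p = 0.519 with an estimated correlation). The largest subunit POLR2A fell from 171.9 ± 4.99 to 117.5 ± 4.36 CPM, POLR2L and POLR2E fell (log2 fold changes -1.22 and -0.52), and the elongation factor TCEA1 rose by 1.67 ± 0.05.

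Stress genes that ATF4 controls rose. Of 33 targets of ATF4 in the integrated stress response, 31 rose and 1 fell (median 1.19, camera adjusted p = 3.76e-21, but adjusted p = 0.105 with an estimated correlation). Besides GDF15, DDIT3, which encodes the factor CHOP, rose from 27.2 ± 1.27 to 145.8 ± 9.59 CPM, the cystine transporter SLC7A11 3.0-fold and the mitochondrial enzyme PCK2 2.58-fold. DDIT4, an inhibitor of mTORC1 that hypoxia also induces, was the member that fell (-0.79 ± 0.04), and CBS did not pass (0.06 ± 0.255). In the unfolded protein response, 21 of 22 genes rose (median 0.55, camera adjusted p = 1.47e-13, but adjusted p = 0.0782 with an estimated correlation). SEL1L, part of the degradation machinery of the endoplasmic reticulum, rose from 104.2 ± 1.54 to 318 ± 21.2 CPM, and ERN1, HERPUD1 and ATF6 rose by 1.73, 1.49 and 0.99 on the log2 scale, while SEC61B fell (-0.20 ± 0.042).

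Other stress lists did not pass as lists. For NRF2 and oxidative stress, 9 of 20 genes rose and 7 fell (camera adjusted p = 0.526), with the ferritin chain FTH1 higher (0.82 ± 0.037) and PRDX1 and PGD lower (-0.83 and -0.59). In heat shock, 5 of 18 rose and 8 fell, or 9 fell adjusted over the list alone (camera adjusted p = 0.497). HSP90AA1 and HSPH1 fell (log2 fold changes -0.59 and -0.49), while HSPA1A and HSPA1B, near-identical copies whose separate values are uncertain, rose by 0.82 and 0.75. Of 23 lysosome and autophagy genes, 10 rose and 8 fell (camera adjusted p = 0.526). WIPI1, an early autophagosome protein, rose from 9.58 ± 0.966 to 54.7 ± 4.57 CPM, and SQSTM1, CTSB and LAMP2 rose by 0.53, 0.61 and 0.51 on the log2 scale. Of 25 apoptosis genes, 9 rose and 7 fell (camera adjusted p = 0.526). The BH3-only gene HRK rose from 24.6 ± 1.45 to 81.9 ± 2.29 CPM, PMAIP1 and XIAP rose by 0.47 and 0.54, and MCL1, which protects from apoptosis, fell (-0.48 ± 0.032). Of 23 immediate early and AP-1 genes, 11 rose and 4 fell (camera adjusted p = 0.12, and 0.0331 with no expression filter, over a range of 0.0331 to 0.534 for the camera alternatives), with KLF4, KLF6, JUN and DUSP1 higher by 0.72, 0.62, 0.44 and 0.69.

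Genes of glycolysis and hypoxia had the lowest median of the lists tested. Of 26, 25 fell and 1 rose (median -1.62, camera adjusted p = 8.29e-20, but adjusted p = 0.135 with an estimated correlation). PGK1 fell from 1219 ± 66.7 to 319.8 ± 3.31 CPM, PKM from 1295 ± 16.9 to 432.1 ± 20.4, and LDHA and ALDOC had log2 fold changes of -2.54 and -4.65. LDHA and PGK1 have pseudogene copies that can take part of their reads. ADM, encoding the vasodilator adrenomedullin, rose (0.75 ± 0.08).

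Genes of lipid synthesis fell as well. Of 25 genes of cholesterol synthesis and other SREBP2 targets, 24 fell (median -1.45, camera adjusted p = 1.11e-20, but adjusted p = 0.0552 with an estimated correlation), and PMVK did not pass (0.06 ± 0.059). IDI1, an enzyme of the mevalonate pathway, fell from 98.3 ± 1.9 to 17.2 ± 0.17 CPM, FDFT1, which makes squalene, from 303.8 ± 8.08 to 82.3 ± 0.659, and ACAT2 and STARD4 had log2 fold changes of -2.06 and -1.996. Of 14 genes of fatty acid synthesis and SREBP1 targets, 13 fell (median -0.80, camera adjusted p = 3.15e-09, but adjusted p = 0.131 with an estimated correlation). The desaturases SCD and FADS2 fell from 905.2 ± 59.5 to 215.9 ± 6.44 CPM and from 824 ± 6.97 to 184.8 ± 10.2, and FASN and ACLY fell (log2 fold changes -0.88 and -0.87). FADS2 and FEN1 share a short stretch of exon on the same strand (2.23% of the exon bases of FEN1).

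Ribosomal protein genes rose slightly and nuclear genes of oxidative phosphorylation fell slightly. Of 30 cytosolic ribosomal protein genes, 26 rose and 1, RPL35, fell, or 2 fell adjusted over the list alone (median 0.18, camera adjusted p = 6.42e-07, but adjusted p = 0.534 with an estimated correlation). RPL3 rose by 0.53 ± 0.035, and RPS14 and RPL10A rose by 0.42 and 0.38. These genes have many processed pseudogenes, so the counts hold only their uniquely placed fragments. Of 27 nuclear oxidative phosphorylation genes, 15 fell (16 adjusted over the list alone) and 3 rose (median -0.18, camera adjusted p = 0.0106, but adjusted p = 0.664 with an estimated correlation), with COX7C, NDUFA1, NDUFA4 and ATP5F1B at -0.68, -0.48, -0.45 and -0.34.

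Mitochondrially encoded RNAs moved apart. Of 15 genes for messenger and ribosomal RNAs, 7 rose and 5 fell (camera adjusted p = 0.526). Copies of mitochondrial DNA in the nuclear genome can take part of their reads. MT-CO1 rose from 10630 ± 209 to 16060 ± 636 CPM, MT-ND4 and MT-CO2 rose by 0.64 and 0.52 on the log2 scale, and MT-ND1 fell from 3005 ± 69.2 to 2025 ± 131 CPM. MT-ND6, which lies on the opposite strand of the annotation (14149 to 14673), was named after its value was seen and fell by 1.44 ± 0.125. Mitochondrial genes together took 7.23 ± 0.281% of the counts with DMSO and 8.27 ± 0.391% with GNF5 (SD, n = 3 each), with no overlap between the groups, although an exact permutation test of 3 against 3 cannot give a p under 0.1.

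**Figure D3:**
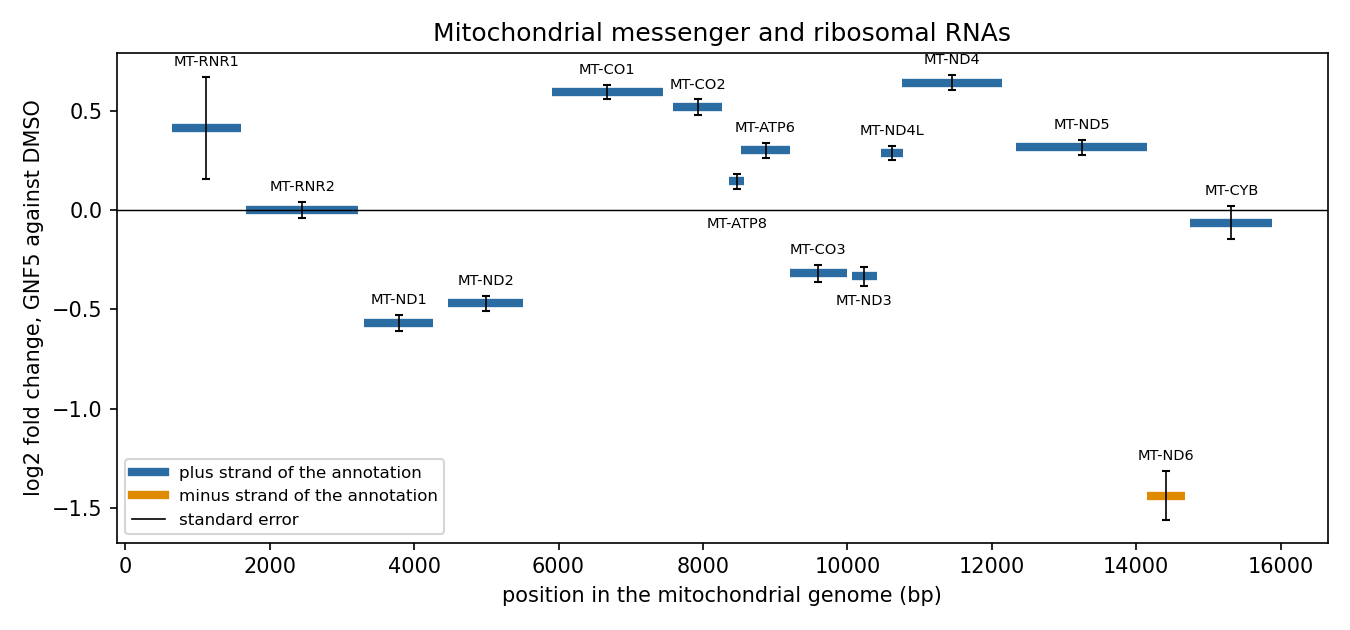
Log2 fold changes (y axis, GNF5 against DMSO, with SE bars) of mitochondrial messenger and ribosomal RNAs at their position in the mitochondrial genome (x axis, bp), with blue bars for the plus and orange for the minus strand. Genes for messenger RNAs on the plus strand lie between -0.57 (MT-ND1) and 0.64 (MT-ND4), and MT-ND6 on the minus strand lies at -1.44.

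Genes of cell identity changed one by one rather than as lists. Of 25 neuroendocrine markers, 10 rose and 10 fell (camera adjusted p = 0.831), and their median (0.02) and mean (-0.08) differ in sign, with the test on the side of the median. SCG2, a granin, rose from 207.8 ± 1.64 to 431.5 ± 13.3 CPM, and DDC, which makes dopamine and serotonin, fell from 248.5 ± 10.5 to 104 ± 3.21. GRP and ENO2 fell (log2 fold changes -1.24 and -0.63). Of 17 non-neuroendocrine and mesenchymal markers, 5 rose and 4 fell, or 3 fell adjusted over the list alone (camera adjusted p = 0.526), with a median of -0.02 but a mean of 0.22 and a test on the side of the mean. ANXA1, EPHA2, CD44 and SNAI2 rose by 1.73, 0.92, 0.49 and 0.34. In NOTCH signalling, 5 of 19 genes rose and 9 fell (camera adjusted p = 0.526), with the ligand JAG1 (0.997 ± 0.051) and the inhibitor DLK1 (0.89 ± 0.085) higher and HES6 and HEY1 lower (-0.96 and -0.38). Of 24 genes of the MYC family and targets, 7 rose and 11 fell (camera adjusted p = 0.362). Besides MYCN and LDHA, the MAX partner MXD4 fell (-1.08 ± 0.047), as did ODC1 of polyamine synthesis (-0.48 ± 0.031). In the interferon response, 11 of 21 genes rose and 4 fell (median 0.31), which did not pass (camera adjusted p = 0.0602, and 0.0405 with no expression filter, over a range of 0.0405 to 0.335 for the camera alternatives). IRF1 rose by 1.05 ± 0.048, HLA-C by 0.76, ISG15 by 1.23 and STAT2 by 0.36, and HLA-C is uncertain because HLA genes share sequence.

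Markers of other cell types gave no common direction. Of 7 fibroblast markers tested, 3 rose and 3 fell (camera adjusted p = 0.792), with COL1A2 and THY1 lower (-0.91 and -0.83) and COL1A1 and POSTN higher (0.87 and 0.24). POSTN was abundant in both groups, at 324.4 ± 10.7 CPM with DMSO and 384.1 ± 10.7 with GNF5. All 4 leukocyte markers tested fell, namely CORO1A, LCP1, PTPRC and CD74, at -0.82, -0.95, -2.25 and -2.51, and the last 2 were under 2 CPM in every library. Of 8 lung epithelial markers, 4 fell and 2 rose (camera adjusted p = 0.526), with KRT7 lower (-0.96 ± 0.079) and MUC1 higher (0.37 ± 0.048). Of 2 erythroid markers tested, SLC4A1 rose (1.92) and HBA2 did not pass (-0.54), and neither this list nor the leukocyte list was large enough for a list test.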

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

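Across the alternatives fixed beforehand and those added after seeing the data (thinning and removal of GC and length trends), counts of higher genes ran from 5215 to 6653 and of lower genes from 5164 to 6733, and no gene was called in the opposite direction to the main test under any of them, while the 1.5-fold test, also added later, called 1240 and 1560. The share of calls that were higher stayed between 47.2% and 51.9%. The stricter filter left 13953 genes to test, which lowered the genes changed at least 2-fold to 907, with 413 higher and 494 lower. Leaving out 1 library at a time gave 2395 to 2610 such genes. With the replicate number as a block, 6279 genes were higher and 6196 lower, and 15 lists passed. Deviations of samples with the same number had correlations of -0.016, 0.016 and 0.001, so the numbers were not taken to pair the samples, and DMSO replicate 1 had its highest correlation with GNF5 replicate 3 (0.025). Lists past the threshold numbered 15 by camera, 4 with an estimated correlation and 28 by fry, which asks a different question. With no filter, 18 lists passed. The test of the fibroblast list turned its direction after thinning (median -0.040, camera adjusted p = 0.971, over a range of 0.548 to 0.971 for the camera alternatives), and its median ran from -0.675 to 0.142 with 1 library left out, and the cause was not tested. Depth limits genes near 0.065 CPM or lower, where a library may hold no more than 3 counts.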

Other observations

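Of the tests here, those of cells of another type and of nuclear copies of mitochondrial DNA were chosen after their results were seen, as were thinning and the removal of GC and length trends as settings.

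The 4 gene families of this paragraph were chosen because many of their members were seen to move one way, so no test of a family as a whole is given, and their counts describe these libraries only. Host genes of small nucleolar RNAs, whose spliced RNAs are usually removed by a translation-dependent decay pathway, rose in 19 of 28 cases and fell in 3 (median log2 fold change 0.56). GAS5 rose from 75.5 ± 1.69 to 281.6 ± 28.8 CPM (SD, n = 3 each) and ZFAS1 from 19.2 ± 0.903 to 70.9 ± 8.65. All 6 tested metallothionein genes, which bind zinc and copper, rose (median 1.92), with MT2A going from 36.5 ± 2.9 to 124.5 ± 20.1 CPM. These genes resemble each other, so their separate values are uncertain. Of 20 genes of heterogeneous nuclear ribonucleoproteins, which package and splice RNA, 16 fell and 0 rose (median -0.29), with HNRNPM at -1.19 ± 0.046. The HNRNP and proteasome families were first taken by the start of the symbol alone and then limited, after these results were seen, by leaving out antisense and other names that are not members. In the wider families 17 of 23 HNRNP genes and 29 of 39 proteasome genes fell. Of 36 proteasome genes, 27 fell and 3 rose (median -0.26). The 3 that rose were PSMB8 (1.40 ± 0.305) and PSMB10 (1.07 ± 0.299) of the immunoproteasome and the assembly factor PSMD5 (0.29 ± 0.043).

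Single genes seen in the table of all genes, and named for that reason, add to this. ASS1, which makes the precursor of arginine, rose from 111.2 ± 6.68 to 654.5 ± 7.44 CPM. IGF2 fell by 2.43 ± 0.301 on the log2 scale beside its imprinted neighbour H19 (-5.40 ± 0.317), which had few counts with GNF5. MEG3 and DLK1 of another imprinted cluster rose by 1.11 ± 0.042 and 0.89 ± 0.085. HIF1A itself rose slightly (0.12 ± 0.039), as did VHL (0.36 ± 0.036), whose product marks HIF1A protein for destruction. LDHAP7, a pseudogene of LDHA with which it shares sequence, was lower by a similar amount (-2.39 ± 0.142). ABCA1 and ABCG1, sterol exporters induced by the LXR receptors, rose by 1.41 ± 0.051 and 1.07 ± 0.039 while SREBF2 fell (-0.68 ± 0.034). A hypothesis is that sterol sensed by LXR lies behind the rise of the exporters. It remains open, since 9 further LXR targets, listed before their values were seen, had a median of 0.388 but did not pass (camera adjusted p = 0.0776, and adjusted p = 0.399 with an estimated correlation). Of these 9, 5 rose and 2 fell. They do not bear on the fall of SREBF2 or of cholesterol synthesis genes, for which a role of sterol was not tested.

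The first pattern weighed is the breadth of the response. After removal of GC and length trends 2400 genes changed at least 2-fold, against 2414, which argues against these trends as the whole source. After thinning every library to the smallest total 2277 did. Totals ran only from 46148701 to 60697602 and edgeR already scales for them. A large drop was therefore unlikely, and thinning decides little about library size. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and 1 of them, the real one, reached its 12782 called genes and its 2414 genes changed at least 2-fold, and the highest of the others gave 0 for both, with edgeR. For lists past the threshold by camera, 2 splits reached 15, and the 9 other than the real one gave 10 to 15. None of the other 9 splits gave a list with an estimated correlation. Each of those 9 mixes the treatments, so part of the treatment difference stays between its groups and the rest widens the spread within them. Their counts are therefore not what chance alone would give, and no conclusion is drawn from them. A response to GNF5, the biological difference of the design, stays open and may be the source, as may any difference in handling that went with the treatment.

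The second pattern is the fall of glycolysis and hypoxia genes beside the rise of ATF4 targets, whose list medians differed by 2.81 on the log2 scale. The difference was 2.855 after removal of GC and length trends, which argues against these as the whole source, and neuroendocrine markers, which dilution of NCI-H69 by other cells would lower about as much as glycolysis genes (median -1.62), had a median of 0.024 with quartiles of -0.472 and 0.322, which argues against dilution as the whole source of the fall. One hypothesis is lower activity of hypoxia-inducible factors, and 20 of their targets outside glycolysis, listed before their values were seen, had a median of -0.956, with 17 lower and 2 higher (camera adjusted p = 1.39e-06 over 4 lists, but adjusted p = 0.18 with an estimated correlation). Another is a response through ATF4 that reaches further genes, and cytosolic tRNA synthetases, with 10 of 16 higher, exceeded the mitochondrial ones, with 5 of 17 higher, by 0.518 in median (camera adjusted p = 1e-05 and 0.366, but adjusted p = 0.0558 and 0.545 with an estimated correlation). Whether cells of another type added to the rise stays open, since 6 of 21 tested markers of such cells rose and 11 fell, as does a change in oxygen use or in the medium, which may act in the same direction and was not tested.

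The third pattern is that genes for mitochondrial messenger RNAs on the plus strand of the annotation, whose RNAs come from one long precursor, moved apart. Of 12 genes, 7 rose, 4 fell and 1 did not pass, over a range from -0.57 to 0.64. These are not 12 separate RNAs, since MT-ND4L overlaps MT-ND4 and MT-ATP8 overlaps MT-ATP6. Even these overlapping genes differed, at 0.287 against 0.641 and 0.144 against 0.301. Fragments that overlap both genes of a pair are left out, so their separate values are uncertain. Reads shared with the nuclear copy of mitochondrial DNA on chromosome 1 can touch only the genes with a copy there. The 5 genes without one still spanned 0.975, which such sharing leaves unexplained for these 5. A share of reads lost alike in both groups would cancel in a fold change, so nothing is concluded for the other genes. The span over the 12 genes was 1.183 after removal of GC and length trends against 1.211. Of 18 mitochondrial tRNA genes, which lie on both strands, 12 fell and 1 rose (median -0.93). They span 59 to 75 bases, and fragments that overlap a neighbouring gene on the same strand are left out. Their highest group mean was 19.7 CPM (MT-TL1 with DMSO), so these counts may not reflect tRNA levels. A change in the processing or stability of mitochondrial RNAs is a candidate explanation that no test here addressed.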
